A study of Mus musculus with 6 samples.

How the data were processed

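Transcript abundance was measured by massively parallel signature sequencing (MPSS) in 6 mouse libraries, 3 from the BLK.CL4 cell line and 3 from liver. In this assay cDNA is cut at DpnII sites (GATC), the 20 bases at the site nearest the 3' end of each cDNA are cloned, every cloned molecule is amplified onto a microbead, and the beads are sequenced in a flow cell. Ideally a signature of 20 bases therefore stands for a transcript, and the number of beads that carry it measures how abundant the transcript was. In these data, as given below, counts also differed between types of run, and miscalled bases may have split some transcripts over several signatures. Per the labels, all libraries came from total RNA of the C57BL6 strain, and each was sequenced in 4 runs. The column headings divide the runs into 2 types, named T and TH, with 2 runs of each per library.

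Per the file headers and from the values, the authors deposited raw bead counts, whole numbers with 1 value per signature and run. The labels describe a conversion to relative transcript abundance for comparisons between samples, but the values used here were not converted. All signatures began with GATC. Per run, the files listed 92.7% to 95.8% of the beads and 67.7% to 84.0% of the signatures that the labels state, so some signatures were left out before deposit by a rule not given in the sources used here. A signature not listed for a library was given a count of 0 there. The base caller and any filter on signature quality are likewise not given in the sources used here.

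Libraries were grouped by the source named in their labels and numbered 1 to 3 within a group. The labels do not say whether the libraries of a group came from separate cultures or animals. P-values therefore measure only the spread between these libraries, which may be technical. The labels give a day for each run. The days that held runs of both groups each held runs of only 1 BLK.CL4 library, which is too few for a comparison within a day.

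Counts of the 4 runs were summed per library. Levels are given as CPM (counts scaled to the same library total in every library, as the name of the unit gives it), as mean ± SD over 3 libraries. Signatures with at least 10 CPM in at least 2 of the 6 libraries were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, group as the only term, two-sided), with TMM factors, a prior count of 5 for fold changes and a Benjamini-Hochberg adjusted p threshold of 0.05. TMM factors lay at 1.72, 1.61 and 1.70 in BLK.CL4 and at 0.604, 0.475 and 0.743 in liver, which shifts fitted log2 fold changes toward liver relative to the ratio of CPM values, while the prior count shrinks those of signatures with few counts in a group. SE values were derived from the F statistic of the test and the log2 fold change at the default prior count of edgeR. They therefore do not belong to the fitted fold changes printed beside them. Where a group had a count of 0 in all its libraries, the fold was computed as a lower bound against the mean CPM that 3 counts per library amount to (1.47 CPM in BLK.CL4 and 1.49 CPM in liver). For signatures higher in BLK.CL4, where TMM factors lower it, the bound is also given with those factors. Such bounds cover counting error only, and because beads carry amplified molecules and some signatures were left out of the files, a count of 0 does not show that a transcript was absent. Measures of library complexity were compared with an exact two-sided permutation test of the difference of means, for which the smallest possible p with 3 against 3 libraries is 0.1. Other computations used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.

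The test was run on simulated counts drawn around the measured means of the 9115 tested signatures and the library totals, with 200 signatures changed in each of 5 draws. It recovered 15.4% of 16-fold changes and 77.6% of 256-fold changes, with 2.4 false calls per draw on average, and the fitted log2 change of the 256-fold set was 0.996 of the true one. In these draws a difference of moderate size was often missed with 3 libraries per group. With only 200 signatures changed, the adjusted p threshold asked for smaller p-values than in the data, where 2732 signatures passed. These shares therefore do not give the power of the test on the data.

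The design, the test and most alternatives were fixed before the data were examined. The rule for naming was fixed then for genes and was applied here to signatures. Named are, in each direction, the 5 signatures with the largest fitted fold change among those that passed the test without overlap between the groups, and in each group the 3 signatures with the highest mean level. Signatures were to be assigned to genes by matching them to transcript sequences. No transcript or genome sequence was used here, and so the tests of genes, of the fixed gene lists and of the position of signatures within transcripts were not run, and results are given by signature. Alternatives were no filter or a stricter filter, prior counts of 1 and 20, DESeq2 1.42.0 size factors, library totals without TMM factors, the DESeq2 test, a replicate block, each run type alone, only signatures seen in at least 2 runs of a library, signatures merged on their first 17 bases, each library left out in turn, and 2 libraries with related codes left out together.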

Results

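Signature abundance was compared between BLK.CL4, a fibroblast line established from C57BL/6 mouse embryo, and mouse liver, with 3 libraries of each. The BLK.CL4 libraries held 1890287, 2051367 and 2187783 counts and the liver libraries 1724799, 2004290 and 2440849 counts, from runs of 373551 to 757941 counts. At these depths 3 counts amounted to 1.23 to 1.74 CPM. The libraries listed 69349 distinct signatures, of which 48572 (70.0%) occurred in only 1 library and 2286 in all 6. Across tested signatures, the Pearson correlation of log2(CPM + 5) was 0.702 to 0.793 among the BLK.CL4 libraries, 0.726 to 0.771 among the liver libraries, and -0.0068 to 0.102 between the groups (signatures are not independent replicates). The filter also kept signatures that reached 10 CPM in only 1 of the groups, which lowers the correlation between the groups. These values therefore do not show that levels in liver and BLK.CL4 were unrelated.

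Liver RNA was dominated by few transcripts, whereas that of the cell line was spread over many. The 10 most abundant signatures held 36.6% ± 6.19 of the counts in liver and 9.23% ± 0.950 in BLK.CL4 (mean ± SD, n = 3 each), and the 100 most abundant held 61.6% ± 6.40 and 34.8% ± 3.71. The 1 most abundant liver signature, GATCCCTGGTGGAAAGGCGG, alone made up 21.2%, 14.3% and 13.9% of liver replicates 1, 2 and 3, and the highest share of any signature in a BLK.CL4 library was 1.87%. Of the liver counts, 50% lay in 41.7 ± 26.3 signatures, against 326 ± 128 signatures in BLK.CL4. The liver values were 26, 27 and 72, with a mean of 26.5 without replicate 3. BLK.CL4 libraries listed 25049 ± 5985 signatures and liver libraries 13558 ± 4599. At an equal depth of 1724799 counts the expected numbers were 24447 ± 5815 and 13260 ± 4385. For each of these measures the 3 values of one group lay apart from the 3 of the other (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 libraries can give), so none can pass a threshold of 0.05. Replicate 2 of each group listed the most signatures of its group (31506 in BLK.CL4 and 17721 in liver). Of the signatures that the labels state, the files listed 67.7% to 77.0% in liver runs and 74.6% to 84.0% in BLK.CL4 runs. The numbers of listed signatures, also at equal depth, are not corrected for this difference.

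**Figure D1:**
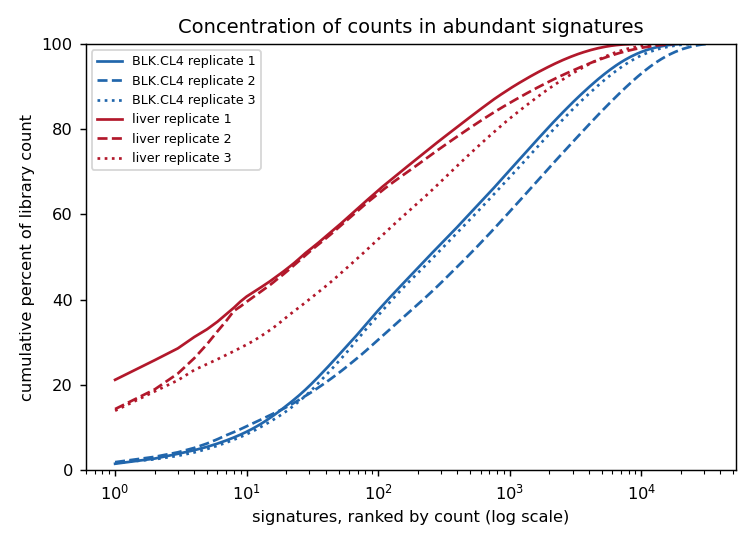
Cumulative percent of each library's counts (vertical axis) held by its signatures ranked from the most to the least abundant (horizontal axis, log scale), 1 line per library, BLK.CL4 in blue and liver in red. The 3 liver lines start at 13.9% to 21.2% with the most abundant signature and stay above the 3 BLK.CL4 lines, which start at or below 1.87%.

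Signature levels of liver and BLK.CL4 differed widely, and the differences went both ways. Of 9115 signatures tested, 2732 passed, with 1359 higher in liver and 1373 higher in BLK.CL4. The signatures higher in liver held 74.2% ± 3.64 of all liver counts and 4.18% ± 1.12 of BLK.CL4 counts. Those higher in BLK.CL4 held 27.0% ± 0.699 of BLK.CL4 counts and 0.707% ± 0.234 of liver counts. The division into directions depended on the settings: 49.7% of the passing signatures were higher in liver here, 31.5% with library totals in place of TMM factors (1048 higher in liver and 2283 higher in BLK.CL4), 70.2% with no filter (1381 and 586) and 61.7% in TH runs only (850 and 527). The median log2 fold change of all tested signatures, at the default prior count of edgeR, moved from -0.67 with TMM factors to -2.13 with library totals. With only T runs, only TH runs or only signatures seen in at least 2 runs, 1322, 1377 and 1447 signatures passed.

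**Figure D2:**
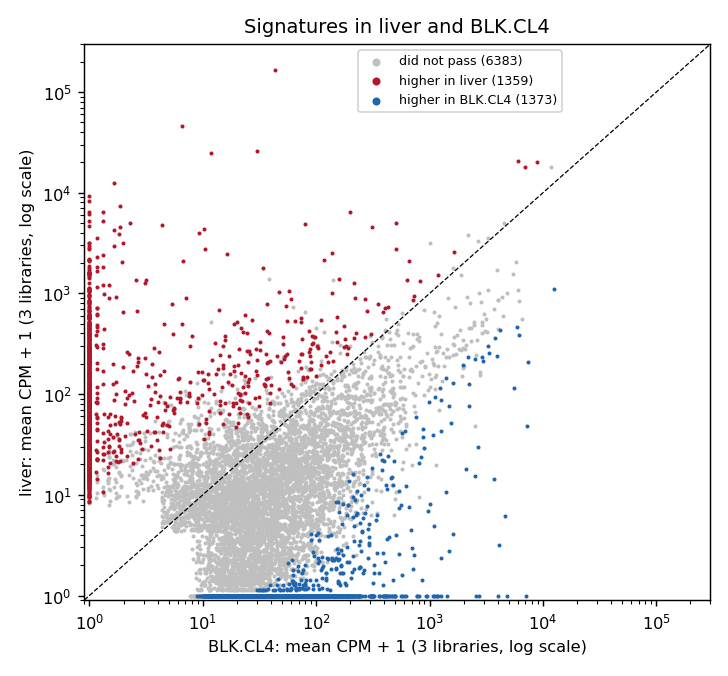
Mean CPM + 1 over 3 libraries in BLK.CL4 (horizontal axis) and liver (vertical axis) for the 9115 tested signatures, both on log scales, with the line of equal levels dashed. Red points are the 1359 signatures higher in liver and blue points the 1373 higher in BLK.CL4, and many of both lie on an axis at a mean of 0 in the other group.

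The 3 most abundant liver signatures had at most 141 counts in any library of the cell line. GATCCCTGGTGGAAAGGCGG stood at 164845 ± 40809 CPM in liver and 42.6 ± 34.0 CPM in BLK.CL4, a 3868-fold ratio of CPM (fitted log2 fold change 13.30, SE 1.44, adjusted p = 0.000755). GATCTGCATTCCATCCTGTC was the next most abundant, at 45831 ± 472 CPM in liver against 5.52 ± 9.57 CPM in BLK.CL4 (fitted log2 fold change 13.78, SE 2.32, adjusted p = 0.00385), and its BLK.CL4 level came from 34 counts in replicate 2 alone. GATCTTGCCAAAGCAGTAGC followed at 26166 ± 1585 CPM in liver and 29.1 ± 26.4 CPM in BLK.CL4 (fitted log2 fold change 11.14, SE 1.85, adjusted p = 0.00413). GATCTGCTCTCCACCTGTCT reached 12436 ± 2450 CPM in liver and had 4 counts in BLK.CL4, all in replicate 2 (adjusted p = 0.000688). A count of 0 in every BLK.CL4 library was found for GATCCCACACATAAATGACT, at 9237 ± 4427 CPM in liver and thus at least 6268-fold higher there, and for GATCAACCACTGCAAATTCA, at 8187 ± 3176 CPM in liver and at least 5556-fold higher (adjusted p = 0.000665 for each). The call of GATCCCACACATAAATGACT was lost when only signatures seen in at least 2 runs were kept, although the fitted log2 fold change was 12.35 there against 12.80 (adjusted p = 0.0585, range over 18 alternatives 6.82e-117, with no filter, to 0.0585), and those of the other 5 passed under every alternative in which they were tested. GATCCCACACATAAATGACT and GATCAACCACTGCAAATTCA had no count in any T run, so that their levels rest on TH runs (60168 and 49607 counts in liver) and they could not be tested in T runs alone. GATCAACCACTGCAAATTCA holds 4-base palindromes at positions 11 and 15, counted from 1 at the first base, and GATCCCACACATAAATGACT holds none after its GATC.

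The signatures with the largest differences toward the cell line had a count of 0 in all 3 liver libraries and lower levels than their liver counterparts. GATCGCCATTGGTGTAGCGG stood at 7012 ± 3238 CPM in BLK.CL4, at least 4711-fold higher than in liver by CPM and at least 1652-fold with TMM factors (fitted log2 fold change -10.96, adjusted p = 0.000688). GATCTTCCCTGTTGGCTGTG, at 4002 ± 389 CPM, was the most even across the BLK.CL4 libraries and at least 2689-fold higher by CPM and 932-fold with TMM factors (fitted log2 fold change -10.13, adjusted p = 0.000665). GATCAGCGCCTCCAGTTCCT, at 2725 ± 750 CPM, and GATCTACAATGAAGCTCTGA, at 2547 ± 561 CPM, were at least 1831-fold and 1712-fold higher by CPM, and 632-fold and 593-fold with TMM factors (fitted log2 fold changes -9.57 and -9.48, adjusted p = 0.000688 for each). GATCTATTGAAAGTCAGCCC varied strongly within the cell line, at 3972, 10064 and 285 CPM in replicates 1, 2 and 3, and was on average at least 3207-fold higher by CPM and 1137-fold with TMM factors (fitted log2 fold change -10.42, adjusted p = 0.00511). These 5 signatures passed under all 19 alternatives.

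The 3 most abundant BLK.CL4 signatures, in contrast, were all abundant in liver too. GATCCATCTGCATTTGCGGC was 11.1-fold higher in BLK.CL4 by CPM, at 12410 ± 6032 against 1115 ± 263 CPM in liver, while the tested log2 fold change with TMM factors was smaller, at -1.9996 (SE 0.57, adjusted p = 0.0380). Its call was lost without BLK.CL4 replicate 1 or 3 or without any 1 of the liver libraries, with log2 fold changes of -1.72 to -2.12 in those fits (adjusted p over all alternatives 0.000124, with no filter, to 0.0927). GATCAACAAATCTCCTAGGC did not pass, at 11869 ± 6936 CPM in BLK.CL4 and 17836 ± 13778 CPM in liver (fitted log2 fold change 2.24, SE 0.88, adjusted p = 0.0856), and its fitted log2 fold change was -0.58 in T runs alone (adjusted p = 0.633). In liver it had 8940 counts in T runs and 96695 in TH runs, and in BLK.CL4 38389 and 33357, so its liver level rests mostly on TH runs. It passed as higher in liver in TH runs alone (log2 fold change 2.98, adjusted p = 0.0390), merged on 17 bases (2.85, adjusted p = 0.0441) and with no filter (2.02, adjusted p = 4.36e-08). Its levels overlapped between the groups, and the p-value without a filter is not read as strength of evidence. GATCAAACTTTACCATTATT was higher in liver at 20368 ± 14704 CPM against 8941 ± 5038 CPM (fitted log2 fold change 2.84, SE 0.89, adjusted p = 0.0461). That call was lost under 11 of 19 alternatives, of which the changed prior counts could not lose it. Log2 fold changes were 1.19 (library totals only, adjusted p = 0.225) to 3.20 in the fits that lost it. The adjusted p over all alternatives was 1.76e-13, with no filter, to 0.225. Both signatures varied within the groups in the same way. In replicates 1, 2 and 3, GATCAACAAATCTCCTAGGC stood at 12114, 18679 and 4813 CPM in BLK.CL4 and 14836, 32868 and 5805 CPM in liver. GATCAAACTTTACCATTATT stood at 11148, 12500 and 3176 CPM in BLK.CL4 and 18093, 36078 and 6934 CPM in liver.

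Abundant signatures passed more often than rare ones. Among 235 signatures with a mean of at least 1000 CPM in the higher group, 62.1% passed, 95 higher in liver and 51 higher in BLK.CL4. Between 100 and 1000 CPM, 469 of 1760 were higher in liver and 319 higher in BLK.CL4. Between 10 and 100 CPM, 784 of 6562 were higher in liver and 989 higher in BLK.CL4. Of 558 signatures under 10 CPM, 4.48% passed. The filter asked for at least 10 CPM in 2 libraries, so below a mean of 10 CPM it kept only signatures whose levels differ within a group. Higher counts also give the test more power. The shares therefore do not show that abundant transcripts differ more often between the groups. Which direction prevailed among abundant signatures depended on scaling: with library totals only, 86 of those with at least 1000 CPM were higher in liver and 109 higher in BLK.CL4, and between 100 and 1000 CPM these numbers were 383 and 597.

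Signatures counted in only 1 of the groups were taken where they had at least 10 CPM in all 3 libraries of that group. So limited, they made up a larger part of liver counts than of BLK.CL4 counts. Signatures of only 1 group at lower or less even levels were not included. At least 10 CPM in all 3 liver libraries together with a count of 0 in all BLK.CL4 libraries was found for 535 signatures, which held 18.7% ± 1.31 of liver counts. The converse held for 751 signatures, which made up 9.15% ± 1.69 of BLK.CL4 counts, and the 3 liver values (17.5% to 20.1%) lay above the 3 BLK.CL4 values (7.72% to 11.0%). All of these signatures passed the test in their direction, as their selection makes nearly certain, and with the DESeq2 test 750 of the 751 in the BLK.CL4 set passed. A further 945 signatures had at least 10 CPM in all 6 libraries and held 47.4% ± 6.45 of BLK.CL4 counts and 27.9% ± 3.25 of liver counts. Of these shared signatures 127 were higher in liver and 34 higher in BLK.CL4 with TMM factors, but 37 and 196 with library totals only. The remaining ones did not pass, which with 3 libraries per group does not show that their levels were alike.

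The run type in which a signature was counted limits the levels given here, for some signatures far more than for others. In each library 68.1% to 79.7% of the signatures, holding 19.8% to 25.6% of the counts, were counted in only 1 of the run types. This includes the 41.0% to 53.9% of the signatures that were counted in only 1 run, which could not appear in both types. Across tested signatures, levels correlated at 0.737 to 0.902 between runs of the same type within a library and at 0.188 to 0.251 between the types. Among 8519 signatures with at least 100 counts over all libraries, a 4-base palindrome starting at position 3, 7, 11 or 15 (counted from 1 at the first base of the signature) went with a missing count in T runs. Of 799 signatures with such a palindrome 69.0% had no T count, against 11.9% of 7720 without. For TH runs the same held for positions 4, 8, 12 and 16, with 66.0% of 739 signatures against 8.35% of 7780. In BLK.CL4 alone the shares for T runs were 65.5% and 10.1%, and in liver alone 81.6% and 16.3%. These positions were chosen after the data were seen and on the same signatures, so no p-value is given.

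**Figure D3:**
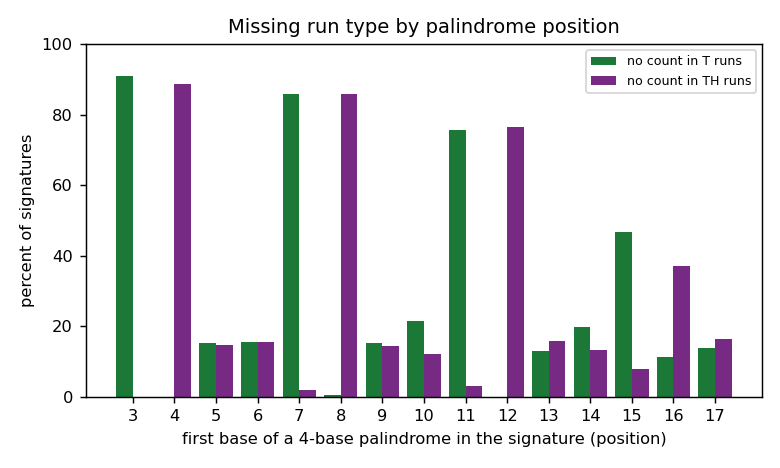
Percent of signatures with at least 100 counts over all libraries that had no count in T runs (green) or in TH runs (purple), by the position of the first base of a 4-base palindrome in the signature. The share without a T count is 90.8% at position 3, 85.8% at 7 and 75.7% at 11, and the share without a TH count is 88.7% at position 4, 85.9% at 8 and 76.4% at 12, whereas at the last position of each frame these shares are 46.7% (position 15) and 37.0% (position 16).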

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

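The stricter filter, library totals, separate run types, signatures in at least 2 runs, merged signatures, the DESeq2 test, the omission of replicate 2 of both groups and the equal-depth count were chosen after seeing the data. Of 2732 signatures passing (1359 higher in liver and 1373 higher in BLK.CL4), fewer passed at 25 CPM in 3 libraries (1416, as 742 and 674, of 3716 tested), in T runs (1322, as 712 and 610), in TH runs (1377, as 850 and 527) and with signatures in at least 2 runs (1447, as 666 and 781). The number higher in BLK.CL4 alone moved with no filter (586), library totals (2283) and the DESeq2 test (2069, with 146 signatures given no adjusted p), and to 864 without liver replicate 2, with 864 to 1228 over the libraries left out in turn. Tested were 7508 signatures in T runs, 7944 in TH runs and 8359 with signatures in at least 2 runs, against 9115. The cause of these shifts was not tested. Leaving out each library gave 1839 to 2233 signatures in all, kept 1567 to 1968 of the original calls and reversed none, but only 1096 were called in all 6 of these fits, and 2385 passed without replicate 2 of both groups. The other settings, the replicate block aside, moved none of these 3 counts by over 1.5 times, and the prior counts could not move them. Every measure of complexity kept its direction, but at 10 CPM or more the libraries listed 8855 signatures in BLK.CL4 and 4758 in liver, a mean difference of -4097 against -11491.

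A replicate block by a letter of the library code (x, N or P) put BLK.CL4 replicate 3, whose code holds both P and N, with the P-coded liver library, a choice the labels do not settle. It gave 1914 signatures, 676 of them higher in BLK.CL4 and 64.7% higher in liver. Same-letter libraries deviated together for N (0.170) and P (0.166) but not for x (0.0028), and over the 317 signatures with at least 50 CPM in all 6 libraries these correlations were 0.504, 0.595 and -0.017, so not every pair passed 0.1 and the letters were not taken to pair the samples. Of the 6 possible matchings, however, the one by letter had the highest mean correlation. It was 0.1128 against at most 0.0606 for the others, and 0.3608 against at most 0.1885 over the 317 signatures. A pairing of the N and P libraries thus stays open. Each library's deviation was taken from the mean of its group, so these correlations depend on each other. The N and P values and the matching are therefore not separate pieces of evidence. Among named signatures, only GATCAACAAATCTCCTAGGC reversed, to -0.58 in T runs. It holds a 4-base palindrome at position 15, 1 of the positions that went with missing T counts. Its liver counts lay mostly in TH runs (96695, against 8940 in T runs), while those in BLK.CL4 did not (33357 and 38389). The cause of the reversal was not tested. The planned tests of genes, gene lists and signature position, with their alternatives, were not run. Depth limits levels below 1.23 to 1.74 CPM.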

Other observations

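All tests in this part were chosen after the results were seen. Traces of the most abundant liver signatures were counted in the cell line. The 10 most abundant liver signatures among those under 100 CPM in every BLK.CL4 library held 35.7%, 28.7% and 29.1% of the counts of liver replicates 1, 2 and 3. In BLK.CL4 their summed counts were 130, 297 and 122, or 0.00688%, 0.0145% and 0.00558% of replicates 1, 2 and 3, and 7, 3 and 8 of the 10 had a count of 0. At an equal depth of 1724799 counts the expected numbers of signatures were 19473, 30841 and 23029 in BLK.CL4 replicates 1, 2 and 3, and 8621, 17337 and 13824 in the liver replicates. A set of 74 signatures within 2 base differences of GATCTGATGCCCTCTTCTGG, chosen after its values were seen, summed to 5429, 10820 and 3104 CPM in BLK.CL4 replicates 1, 2 and 3 and to 1161, 3614 and 1416 CPM in the liver replicates.

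The division of the libraries into BLK.CL4 and liver gave 2732 signatures, and the highest count among the other splits into 3 against 3 was 0. Only the real split, 1 of 10, reached its count, but 10 splits are too few for a share under 0.05. Every other split also put BLK.CL4 and liver libraries together on each side, which widens the spread within a side. Few calls were thus built into those splits, and the contrast with 0 cannot tell whether chance plays a part.

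Many signatures were counted in only 1 run type. Low counts are argued against as the whole cause, since 18.0% of the 1525 signatures with at least 1000 counts lacked a run type. A 4-base palindrome in the frame of the missing run type went with a higher share with no count, by a ratio of 5.79 for T and 7.90 for TH runs over all libraries, and of 4.996 for T runs in liver alone. A candidate explanation is that such ends pair with each other during the ligation steps of sequencing and are lost, with the run types reading in frames that are offset from each other. Palindromes were present in 37.5% of the signatures without T counts and 42.9% of those without TH counts, so the others stay open, and no biological explanation was tested.

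The last base of an abundant liver signature differed between runs of the same library in liver replicates 2 and 3. GATCTTCCAGGCCCGCCTCA and GATCTTCCAGGCCCGCCTCC differ by A20C, and the share of the first spread over 2.83% to 96.5% in the runs of liver replicate 3 and 11.4% to 94.4% in those of replicate 2, but only 93.3% to 98.2% in replicate 1. The spread of 93.7 percentage points in replicate 3 argues against a pair of transcripts or alleles in the RNA as the cause, since all runs read the same library. Miscalled last bases in single runs may be the cause, because the CV of the summed level was at most 0.804 of the CV of the first ending in every liver library. Among 77 signatures with at least 20000 counts, a partner with at least 1% of the count and a single difference occurred at position 20 in 46.8%, at position 19 in 35.1%, and at each of positions 5 to 18 in at most 11.7%.

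Replicate 2 of each group, with an N in its library code, and replicate 3 of each group, with a P (and in BLK.CL4 also an N), differed in a way that the cell line and liver shared. Across 317 signatures with at least 50 CPM in all 6 libraries, the log2 difference of replicate 2 over replicate 3 (N over P) correlated between the groups at r = 0.62 (bootstrap 95% interval 0.54 to 0.69 over signatures, which are not independent replicates), with 20 signatures at least 2-fold higher in N in both, 72 at least 2-fold higher in P in both and 2 opposite. GATCAACAAATCTCCTAGGC and GATCAAACTTTACCATTATT, named above, are among the 20. Run type, split signatures and GC content of the signature are argued against as the whole cause, since r was 0.648 with the groups taken from opposite run types (128 signatures with at least 50 CPM in both types, but 0.23 and 0.35 over all 317), 0.653 with signatures merged on 17 bases and 0.614 with GC content of the signature held fixed. The GC content of whole transcripts was not tested. A difference in how the RNA or the libraries of each code were made could underlie it and stays open, because the labels do not say what the letters mean, and no biological explanation was tested.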
